A study of Homo sapiens with 6 samples.

How the data were processed

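The series compared Huh7 hepatocellular carcinoma cells transduced with a lentiviral LHX2 vector with cells transduced with a control vector, in 3 libraries each, at 48 h. Per the labels' protocols, RNA was isolated with a column kit and libraries were made with a stranded mRNA kit, so that polyadenylated transcripts were measured. Per the submitters' processing notes, the authors used bcl2fastq 2.20, FastQC, TopHat2 2.1.1, Bowtie2 2.3.5.1, SAMtools 1.9 and featureCounts 2.0.0 with the human builds GRCh38/hg38. The gene annotation and the strand setting are not given in the sources used here. The deposited values were raw counts of reads per gene for each library, whole numbers without normalization. The table held 28265 genes, 0 of them without a name and 0 duplicated, and all its per-sample columns were used. The name of 1 control column was written in another form than those of the other control columns, and it was taken as control replicate 1 by the number it ends in and because the other control columns carry the other numbers.

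Genes were matched to a RefSeq gene annotation for positions and biotypes: 27966 by gene identifier, 136 by a current or older symbol, and 163 without a match. The match did not decide which genes were tested. Transcript length and GC content were those of the longest transcript of each gene in the GENCODE annotation of GRCh38 (release 29). Total counts per library ran from 30029313 to 39653681. At this depth the 10 genes with the most counts took 7.07% to 7.48% of a library. Exact binomial intervals for ratios of summed counts, scaled by the totals, were given at 95% and cover counting error only, since reads without molecular identifiers are not independent molecules.

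Low counts were removed with edgeR filterByExpr (min.count 10, min.total.count 15, min.prop 0.7), which left 14533 genes. Libraries were scaled with TMM factors, which lay between 0.985 and 1.02. Groups were compared with the edgeR quasi-likelihood F-test with the group as the single term, and p-values were adjusted over all genes tested by the Benjamini-Hochberg method at a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic, and CPM values are TMM-scaled. Log2 CPM for the list tests and principal components used a prior count of 2. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.

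The design, the alternatives, the rule for named genes and 35 gene lists with 962 memberships were fixed before the data were examined, and 947 memberships had a row in the table. Named genes were LHX2, the 12 highest and 12 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean of at least 5 CPM, an official symbol and no overlap between the groups, up to 4 members of each list with the largest changes, and pathway genes of the series title, of which CTNNB1 and MAPK3 are given. Some genes that the rule names are not reported here. Genes named outside that rule were chosen after their values were seen: EGR1, FOS, AXIN2, RPS6KA3, MAP2K1, RNF43, GLUL, OAT, FZD4, VIM, CDH1, NOTCH2, FGA, FGG, SLCO1B1, SULT2A1, HNF4A, GPC3, HK2, HSPA5, STAT2, IFI35, DTX3L, SSBP3, SLIT2, SNAP25 and RPS12. Lists with at least 3 tested members, 33 of the 35, were tested with limma camera at a preset inter-gene correlation of 0.01, again with the correlation estimated from the data, and with fry. Lists share members and are not independent of each other. The list of mitochondrially encoded genes was not analysed here because the table held no row for its 13 members, and the endothelial list had 1 tested member.

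The alternatives were RLE and upper-quartile factors, library totals alone, LHX2 left out of the totals and factors, no filter on low counts, a filter of 1 CPM in 3 libraries, a replicate block, each library left out, DESeq2, limma-voom, glmTreat against a 2-fold change, and the lists without LHX2 and shared members. Removal of a trend with transcript length and GC content was added after the data were seen. It used a loess surface (span 0.3) per library, fitted on genes with a log2 CPM over 1. It was first run without centring, and the form centred on each library's median was added after that result was seen. The test was also tested on simulated data with 14360 genes: 23 of 50 genes changed 1.2-fold, 35 of 49 changed 1.5-fold, 44 of 50 changed 2-fold and 50 of 50 changed 4-fold were recovered, and 19 of 14126 unchanged genes were called. A simulated length trend with no changed gene gave 2685 calls before the trend correction and 2 after it.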

Results

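RNA was profiled by sequencing in Huh7 cells, an established human hepatocellular carcinoma line, 48 h after transduction with a lentiviral vector that expressed LHX2 or with a control vector. LHX2 encodes a LIM-homeodomain transcription factor. Each group held 3 libraries, and the deposited read counts summed to 32625405, 39653681 and 32981204 in control replicates 1 to 3 and to 30029313, 30351710 and 35194438 in LHX2 replicates 1 to 3. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. A single comparison follows from this design, LHX2 against control vector, and the series title directs it to the MAPK/ERK and Wnt/beta-catenin pathways.

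LHX2 itself, on chromosome 9 from position 124011768 to 124033301 of GRCh38, had 1, 2 and 1 counts in the control libraries and 2535, 2427 and 3126 counts in the LHX2 libraries. The LHX2 libraries thus held 83.6 ± 3.61 CPM (read counts scaled by normalised library size; SD, n = 3), and the ratio of LHX2 to control was 2227, with an exact binomial 95% interval of 869 to 8175 that covers counting error only. Among 14533 genes tested, 4716 changed with LHX2 at a Benjamini-Hochberg adjusted p under 0.05 in the edgeR quasi-likelihood test, of which 2415 were higher and 2301 lower. The changed genes were 32.5% of those tested, with 16.6% higher and 15.8% lower, the shares to set beside the list counts below. These shares are not matched for expression. Genes with more counts pass more easily: with a filter of 1 CPM in 3 libraries 4625 of 12656 genes were called. Lists of abundant genes can therefore exceed these shares without larger changes. Most changes were small, with a median absolute log2 fold change of 0.30 among the genes that changed, and 958 of them moved at least 1.5-fold. A change of at least 2-fold was fitted for 373 genes, 273 higher and 100 lower, and 122 genes passed a test against a 2-fold change (edgeR glmTreat). The groups did not overlap in 6532 genes, 44.9% of those tested, where chance gives 10%. The share of higher genes among those that changed, 51.2%, depended on the processing. It was 59.8% with library totals alone. After a trend with transcript length and GC content was removed, an alternative added after the data were seen, it was 44.9% (2276 higher, 2793 lower) with the correction centred per library and 40.5% (2098 higher, 3081 lower) without centring.

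The largest rises were ranked among genes with a mean of at least 5 CPM and no overlap between the groups. CGA, the alpha subunit of the glycoprotein hormones (chromosome 6, 87085498 to 87095106), rose 20.3-fold, from 3.82 ± 0.153 to 77.5 ± 9.15 CPM (SD, n = 3; edgeR adjusted p = 1.4e-13). NTS, the precursor of neurotensin, rose from 1056 ± 13.3 to 5674 ± 250 CPM (SD, n = 3), and VCAN, the matrix proteoglycan versican, rose 4.93-fold to 679 ± 38.9 CPM. SH3BP5, which binds the SH3 domain of BTK, rose 11.7-fold, and SPOCK2, a matrix proteoglycan, 10.7-fold. Log2 fold changes of 3.10 for ZPLD1, 2.84 for FSTL1, 2.70 for LRRC31, 2.69 for the lipoprotein receptor VLDLR and 2.61 for SAMD11 followed, and SLC2A2, the hepatocyte glucose transporter GLUT2, and the protease gene ADAMTS6 completed the 12 highest at 4.94-fold and 4.93-fold.

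The largest falls were ranked under the same rule. SGK1, a serum- and glucocorticoid-inducible kinase, fell from 164 ± 1.12 to 50.4 ± 0.538 CPM (3.25-fold lower, edgeR adjusted p = 1.6e-13), and MYCN, a MYC-family transcription factor (chromosome 2, 15940550 to 15947004), from 96.0 ± 3.84 to 32.8 ± 1.66 CPM (2.93-fold lower). PLAU, the urokinase plasminogen activator, was 4.16-fold lower and the urea-cycle enzyme gene ARG1 2.57-fold lower. Log2 fold changes were -2.06 for UGT2B4, -1.61 for RBP2, -1.52 for RANBP3L, -1.47 for TFEC, -1.46 for AKR1C1, -1.41 for NEGR1, -1.37 for S100P and -1.34 for RUNX1. UGT2B4 and AKR1C1 have close sequence copies in their families, so reads shared between copies leave their values uncertain.

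**Figure D1:**
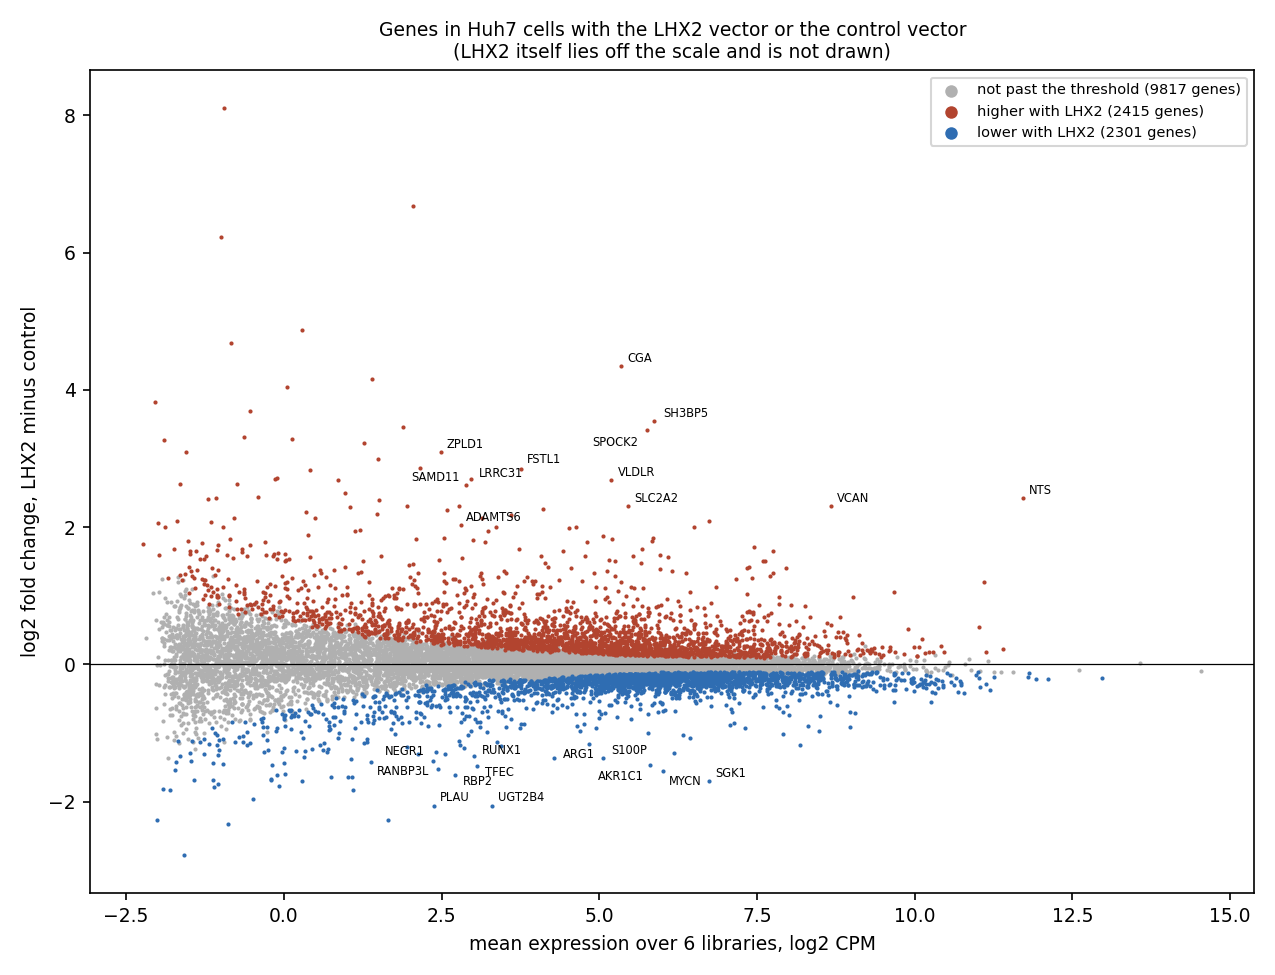
Each point is a gene, with its mean expression over 6 libraries (log2 CPM) on the horizontal axis and its log2 fold change, LHX2 minus control, on the vertical axis; 2415 genes were higher (red), 2301 lower (blue), and the genes in grey did not pass the edgeR test. CGA (4.34) is the highest and UGT2B4 (-2.06) the lowest of the labelled genes.

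**Figure D2:**
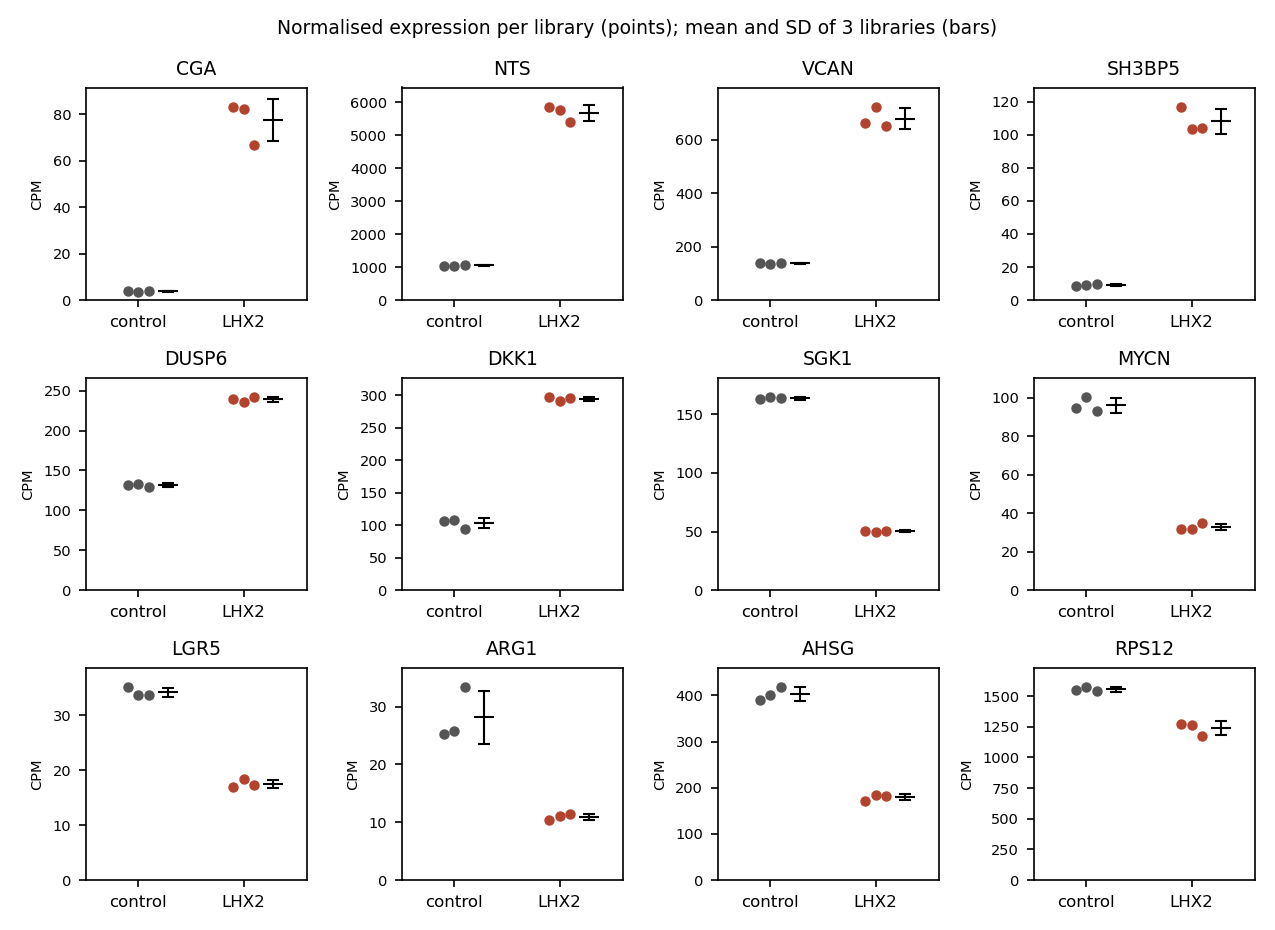
Normalised expression (CPM, axes from 0) of 12 genes in each of the 3 control and 3 LHX2 libraries (points), with the mean and SD of each group (bars). The LHX2 libraries lie above all control libraries for CGA, NTS, VCAN, SH3BP5, DUSP6 and DKK1, and below them for SGK1, MYCN, LGR5, ARG1, AHSG and RPS12.

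Transcripts that ERK signalling induces were higher for part of the list. DUSP6, a phosphatase that inactivates ERK (chromosome 12, 89347235 to 89352501), rose 1.81-fold, from 132 ± 2.05 to 239 ± 3.41 CPM (SD, n = 3; edgeR adjusted p = 2.6e-10). DUSP4, a related phosphatase, rose 1.69-fold, PHLDA1 1.53-fold and CCND1, which encodes cyclin D1, 1.26-fold. Of 26 tested ERK targets 8 rose and 18 did not pass, with 8 higher adjusted over the list alone, and the median log2 fold change was 0.12. EGR1 (0.42 ± 0.20, SE) and FOS (0.10 ± 0.27) were among those that did not pass, although EGR1 passed at 0.60 without LHX2 replicate 2. The list as a whole did not pass camera, which compares it with all other genes (adjusted p = 0.065, and adjusted p = 0.43 with an estimated correlation). It passed when control replicate 1 (adjusted p = 0.042) or LHX2 replicate 2 (adjusted p = 0.027) was left out or with a filter of 1 CPM in 3 libraries (adjusted p = 0.049), while 6 members were higher and 1 lower without control replicate 3, and 8 higher and 1 lower without LHX2 replicate 3.

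Among receptor tyrosine kinases and components of the RAS-MAPK cascade, 13 of 34 rose, 2 fell and 19 did not pass. RASA1, a GTPase-activating protein of RAS, rose 1.61-fold, the hepatocyte growth factor receptor gene MET 1.41-fold and ERBB2 1.34-fold. RPS6KA3 (log2 fold change -0.41) and MAP2K1 (-0.13) were the members that fell, but MAP2K1 did not pass without control replicate 1 (-0.11), control replicate 2 (-0.14) or LHX2 replicate 2 (-0.10). Adjusted over the list alone, 14 were higher and 2 lower, and the camera adjusted p was 0.18. These counts depended on single libraries, with 6 higher and 1 lower without control replicate 1 or 2, 8 and 2 without LHX2 replicate 2, and 9 and 4 without LHX2 replicate 1. MAPK3, which encodes the kinase ERK1, did not pass the edgeR test and differed by 0.03 ± 0.08 (SE, adjusted p = 0.79).

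Targets of Wnt/beta-catenin signalling moved in both directions, in shares near those of all tested genes (16.6% higher and 15.8% lower). DKK1, a secreted Wnt antagonist and itself a target (chromosome 10, 52314281 to 52317657), rose 2.855-fold, from 103 ± 7.88 to 294 ± 3.64 CPM (SD, n = 3; edgeR adjusted p = 1.2e-11). LGR5, the R-spondin receptor (chromosome 12, 71439129 to 71586310), fell from 34.2 ± 0.874 to 17.6 ± 0.698 CPM (adjusted p = 2.1e-08), and RNF43, a ubiquitin ligase that removes Wnt receptors, fell by 0.29 on the log2 scale. Of 18 tested targets 4 rose, 2 fell and 12 did not pass, with 4 higher and 2 lower adjusted over the list alone. AXIN2, a widely used target gene, differed by 0.05 ± 0.09 (SE, adjusted p = 0.70). The list did not pass camera (adjusted p = 0.33), and CTNNB1, the beta-catenin gene, differed by -0.04 ± 0.04 (SE, adjusted p = 0.47).

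The list of liver beta-catenin targets holds pericentral genes, which beta-catenin induces, and periportal genes, which it represses, so a single direction of the list has no single reading. Of the induced genes LGR5, GLUL, which encodes glutamine synthetase (log2 fold change -0.42), and OAT (-0.34) fell, as did the periportal urea-cycle genes ARG1 and CPS1 (-0.92) and 1 further gene, while the amino acid transporter gene SLC16A10 rose 3.57-fold. That made 1 higher, 6 lower and 5 not passing among 12 tested, and 1 higher and 7 lower adjusted over the list alone, with a camera adjusted p of 0.055. This p was 0.042 without control replicate 1, 0.041 without LHX2 replicate 2, 0.037 with library totals alone, 0.025 without a filter on low counts and 0.011 with the 1 CPM filter. Of 33 Wnt ligands, receptors and other pathway components 9 rose, 3 fell and 21 did not pass, with 9 higher and 4 lower adjusted over the list alone. TCF7L1, a transcription factor of the pathway, rose 1.86-fold, WLS, which carries Wnt proteins to the cell surface, 1.66-fold, and the receptor gene FZD7 1.59-fold, while FZD4 fell by 0.36 on the log2 scale. Their camera adjusted p was 0.065, and it was 0.024 without control replicate 2, 0.049 without LHX2 replicate 2 and 0.041 without a filter on low counts. Without control replicate 3 or LHX2 replicate 1 the counts were 7 higher and 1 lower.

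**Figure D3:**
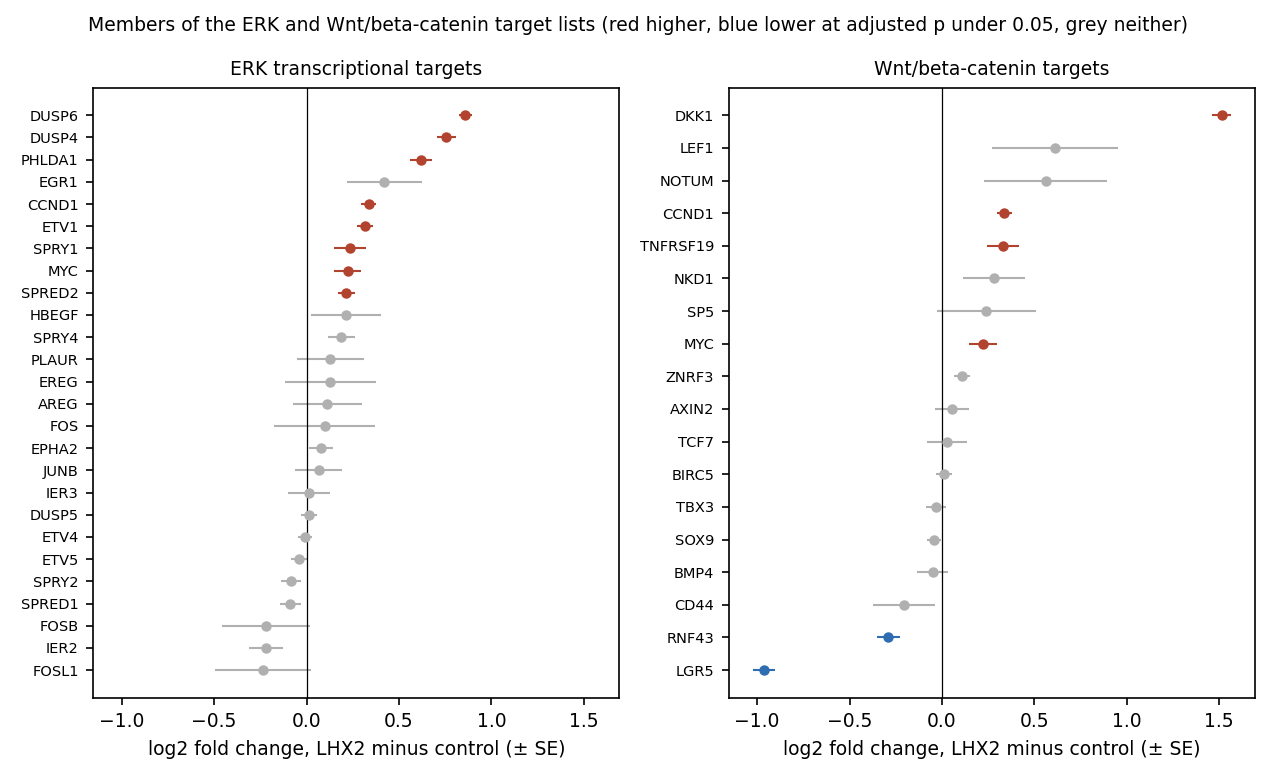
Log2 fold change, LHX2 minus control, with its SE for each tested member of the ERK target list (left) and of the Wnt/beta-catenin target list (right); red points were higher, blue lower and grey neither in the edgeR test. DUSP6 (0.86) and DUSP4 (0.76) lead the first list, and DKK1 (1.51) and LGR5 (-0.96) mark the ends of the other.

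Changes of cell-cycle genes were small. Of 35 S-phase and E2F target genes 7 rose, among them CCNE2 (cyclin E2, log2 fold change 0.51), TK1 (0.38) and E2F2 (0.38), and 28 did not pass, with 6 higher adjusted over the list alone and a camera adjusted p of 0.26. Genes of G2 and mitosis went both ways: 9 of 32 rose, led by CDC25C (0.30) and CDK1 (0.26), 6 fell, led by the kinesin gene CENPE (-0.42), and 17 did not pass (9 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.90), with 5 higher and 5 lower without control replicate 1 and 6 and 3 without control replicate 2. In the list of CDK inhibitors, D-type cyclins and their partners CCND1 and CDK6 (0.19) rose and 12 of 14 did not pass, also with 2 higher adjusted over the list alone (camera adjusted p = 0.18), and CDK6 no longer passed at 0.08 after the length and GC trend was removed. TP53INP1 (1.12) and DDB2 (0.61) rose and AEN (-0.30) fell among 21 p53 targets, of which 18 did not pass (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.24). Among 26 apoptosis regulators 7 rose, 4 fell and 15 did not pass, with the same counts of 7 and 4 adjusted over the list alone, 6 and 2 without control replicate 2, and a camera adjusted p of 0.79. The pro-apoptotic BMF rose (0.55), as did the anti-apoptotic BIRC3 (1.15) and BCL2L1 (0.32), and BID fell (-0.40). BIRC3 had few counts, 14, 18 and 26 in control replicates 1 to 3 and 40, 35 and 45 in LHX2 replicates 1 to 3. Of 17 replication-dependent histone genes HIST1H4B (1.13), HIST1H4H (0.43) and HIST1H1C (0.41) rose and 14 did not pass, with 3 higher adjusted over the list alone (camera adjusted p = 0.055). The libraries measured polyadenylated transcripts, so these values cover only the polyadenylated transcripts of histone genes and may not follow their total expression. HIST1H4B did not pass without control replicate 1 (1.12) or 2 (0.98) or LHX2 replicate 1 (1.02). The histone list passed after the length and GC trend was removed (adjusted p = 6.9e-03), without a filter on low counts (0.037), and at 0.026 to 0.042 when control replicate 1 or 2 or LHX2 replicate 1 or 3 was left out.

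Targets of YAP/TEAD and genes of the matrix had some of the highest list medians, 0.35 and 0.32 on the log2 scale. Of 19 YAP/TEAD targets 13 rose and 6 did not pass, with 14 higher adjusted over the list alone. ANKRD1 rose 4.51-fold, F3, which encodes tissue factor, 2.79-fold, AMOTL2 1.69-fold and CCN1 1.69-fold, and the list passed camera (adjusted p = 1.2e-05, but adjusted p = 0.41 with an estimated correlation). In the list of matrix proteins, integrins and proteases 17 of 31 rose, 4 fell and 10 did not pass (19 higher and 5 lower adjusted over the list alone), with COL4A6 3.99-fold and COL4A5 1.99-fold higher, TIMP3 1.82-fold lower and PLAU lower as given above. That list also passed camera (adjusted p = 5.4e-03, but adjusted p = 0.41 with an estimated correlation). Mesenchymal genes included LOXL2 (log2 fold change 1.95), LOX (0.59) and VIM (0.48) among 6 that rose of 14, while S100A4 fell and 7 did not pass (6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.13). LOXL2 was low, with a mean of 0.935 CPM in the control and 3.68 CPM in the LHX2 libraries. The call for S100A4 (-0.52) was lost without any 1 of the control libraries, LHX2 replicate 2 or LHX2 replicate 3, with values between -0.57 and -0.36, and 7 members were higher and 2 lower without LHX2 replicate 1. Epithelial junction and keratin genes split evenly, with 7 of 21 higher, 7 lower and 7 not passing, and 7 each way adjusted over the list alone. CLDN6 (0.79) and KRT19 (0.53) rose and CLDN2 (-1.26) and CDH1, the E-cadherin gene (-0.35), fell, and the median (0.07) and the mean (-0.01) of the list differed in sign, with camera in the direction of the median (adjusted p = 0.94). CLDN2 was low, with a mean of 0.743 CPM in the LHX2 libraries.

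Signalling ligands and receptors of other pathways also changed. Of 26 angiogenic factors 10 rose, 3 fell and 13 did not pass (10 higher and 3 lower adjusted over the list alone), with EDN1, the endothelin-1 gene, 2.42-fold and VEGFA 1.78-fold higher. The camera adjusted p was 0.069, and it was 0.027 without LHX2 replicate 2, 0.049 without a filter on low counts and 0.044 after the length and GC trend was removed without centring. TGF-beta and BMP pathway genes rose in 11 of 22 cases, including LTBP1 (log2 fold change 0.83), BAMBI (0.70) and BMP2 (0.62), the receptor gene TGFBR2 fell (-0.48) and 10 did not pass, with 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.10). In the Notch pathway MAML3 (0.77), NOTCH3 (0.73), JAG2 (0.63), NOTCH1 (0.47) and NOTCH2 (0.40) were the 5 of 17 that rose, 12 did not pass, and 7 were higher and 1 lower adjusted over the list alone. JAG2 did not pass without LHX2 replicate 3 (0.47), and 1 member was called lower without control replicate 3. Camera gave the Notch list an adjusted p of 0.047, lost with an estimated correlation (adjusted p = 0.44), without control replicate 3 (adjusted p = 0.12) and without LHX2 replicate 3 (adjusted p = 0.075). It was also lost with library totals alone, with either other filter, after the length and GC trend was removed with centring and without shared members, at adjusted p-values between 0.051 and 0.082.

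Genes of hepatocyte function changed in large numbers and in both directions. Of 40 plasma protein genes 17 rose, 16 fell and 7 did not pass, with 17 each way adjusted over the list alone. SERPINA3, alpha-1-antichymotrypsin, rose 3.66-fold and HPX, hemopexin, 2.58-fold, while AHSG, fetuin-A, fell from 403 ± 14.7 to 179 ± 6.41 CPM (SD, n = 3) and the fibrinogen genes FGA and FGG fell by 0.70 and 0.71 on the log2 scale. The median (0.03) and mean (0.04) of the list were positive and its camera test was negative (adjusted p = 0.996). In the list of xenobiotic, bile acid and amino acid metabolism 7 of 34 rose, 16 fell and 11 did not pass, with the same 7 and 16 adjusted over the list alone. CYP2C8 was 3.85-fold higher, SLCO1B1 had a log2 fold change of 1.22, and SULT2A1 (-1.29), TDO2 (-1.96), CPS1, ARG1 and UGT2B4 fell. CYP2C8 also has close copies in its family, so shared reads may leave its value uncertain. The median was -0.27 and the camera adjusted p 0.056, which moved to between 0.032 and 0.042 when any library but control replicate 3 was left out, to 0.027 with library totals alone, to 0.023 without a filter on low counts and to 0.040 with the 1 CPM filter. Of 26 hepatocyte transcription factors 10 rose, 4 fell and 12 did not pass (10 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.41), with ONECUT2 2.66-fold and ONECUT1 1.55-fold higher, CREB3L3 1.43-fold lower and HNF4A at -0.26 on the log2 scale. Oncofetal and progenitor genes had 9 of 25 higher, among them IGF2 (0.80), PROM1 (0.73) and GPC3 (0.25), 5 lower, among them DLK1 (-0.70) and MYCN, and 11 not passing (10 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.70).

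Many of the tested markers of other liver cell types, cells that a culture of Huh7 should lack, changed. Among 6 tested cholangiocyte markers 4 rose, among them ANXA4 (2.64-fold), KRT19 and BICC1, and 2 did not pass, with 4 higher adjusted over the list alone (camera adjusted p = 0.090, or 0.040 with the 1 CPM filter), and 1 was called lower without control replicate 2 or LHX2 replicate 3. Of 5 stellate cell and fibroblast markers COL1A2 (3.98-fold, from 9.26 ± 0.753 to 36.8 ± 1.21 CPM), LUM (1.40-fold) and PDGFRA (1.19-fold) rose and 2 did not pass, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.099), and without control replicate 3 PDGFRA did not pass (0.20) and 1 other member was called lower. CD68 (1.98-fold) and LYZ (1.35-fold) rose among 4 leukocyte markers, 2 did not pass, and 2 were higher adjusted over the list alone (camera adjusted p = 0.18). PECAM1 (-0.41) was the 1 endothelial marker with enough counts to be tested and was lower also adjusted over the list alone. Its call was lost without control replicate 1 (-0.41), control replicate 3 (-0.36) or LHX2 replicate 3 (-0.34), and in DESeq2.

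Many ribosomal protein genes and genes of lipid synthesis fell by small amounts. Of 36 ribosomal protein genes 32 fell and 4 did not pass, with 35 lower adjusted over the list alone, a median log2 fold change of -0.25 and individual values of RPS2 (-0.38), RPL27 (-0.37), RPS14 (-0.36) and RPL23 (-0.36). Camera passed (adjusted p = 1.2e-11), but not with an estimated correlation (adjusted p = 0.41). In the list of cholesterol and fatty acid synthesis 16 of 31 fell, 3 rose and 12 did not pass, with 20 lower and 4 higher adjusted over the list alone, and 14 lower and 1 higher without control replicate 1. INSIG2 (-0.34), IDI1 (-0.30) and MSMO1 (-0.29) fell, and camera passed (adjusted p = 3.2e-03, but adjusted p = 0.43 with an estimated correlation). Glycolysis and hypoxia genes included ENO2 (1.19) and VEGFA (0.83) among 7 higher of 28, HK2 (-0.32) among 3 lower, and 18 not passing (7 higher and 3 lower adjusted over the list alone), with a median of -0.02 against a mean of 0.10 and camera in the direction of the mean (adjusted p = 0.66). That median was 0.01 with library totals alone, where 9 members were higher and 1 lower. In leave-one-out runs 1 member was lower without control replicate 2, control replicate 3 or LHX2 replicate 2, against 5 without LHX2 replicate 1. Of 28 genes of the unfolded protein and integrated stress responses 3 rose, 7 fell and 18 did not pass (4 higher and 10 lower adjusted over the list alone). VLDLR rose as given above, while HSPA5, the chaperone BiP (-0.28), HERPUD1 (-0.29) and SLC7A11 (-0.29) fell, and the median (-0.10) and the camera test (adjusted p = 0.13) were opposite in sign to the mean (0.03). Interferon response genes rose in 5 of 31 cases, including IFIT3 (0.44) and STAT2 (0.27), OAS1 (-0.84), IFI35 (-0.32) and DTX3L (-0.30) fell, and 23 did not pass, with 5 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.94). OAS1 did not pass without control replicate 1 (-0.84) or 3 (-0.78) or LHX2 replicate 2 (-0.84) or 3 (-0.68). IFI35 passed only with all libraries or without LHX2 replicate 1, with values of -0.35 to -0.26 where it did not. The counts were 5 higher and 1 lower without control replicate 3, 4 and 1 without LHX2 replicate 3, 3 and 2 without control replicate 2, and 3 and 4 without LHX2 replicate 1, and the calls of IFIT1 and IRF9 were among those lost.

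Genes related to the family and the developmental roles of LHX2 often had too few counts to be tested in these cells. In the list of LIM-homeodomain factors and their cofactors 5 of 13 tested members rose and 8 did not pass, with 5 higher adjusted over the list alone. Besides LHX2 itself, LMO3 rose 3.58-fold, LMO4 1.61-fold and SSBP3 had a log2 fold change of 0.20, and LHX4 had 20, 16 and 17 counts against 3, 4 and 2. The list passed camera (adjusted p = 6.6e-03, but adjusted p = 0.41 with an estimated correlation, and adjusted p = 0.062 without LHX2 and shared members). Of 34 neural and eye-field transcription factors 8 could be tested: 2 rose, among them EMX1 (1.41), 1 fell and 5 did not pass, with 2 higher and 1 lower adjusted over the list alone, a median of -0.03 against a mean of 0.30 and camera in the direction of the mean (adjusted p = 0.90). EMX1 did not pass without control replicate 2 (1.34), control replicate 3 (1.17) or LHX2 replicate 3 (1.07). Neuronal and axon guidance genes rose in 11 of 20 cases, among them SEMA6A (2.32-fold), SYT1 (2.04-fold), NLGN1 (1.93-fold) and SLIT2 (log2 fold change 0.91), UNC5B (-1.13) and SNAP25 (-0.62) fell, and 7 did not pass, with 12 higher and 3 lower adjusted over the list alone. That list passed camera (adjusted p = 6.4e-03, but adjusted p = 0.41 with an estimated correlation). UNC5B did not pass without control replicate 1 (-0.96) or 2 (-1.15) or LHX2 replicate 1 (-0.94) or 2 (-1.17).

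**Figure D4:**
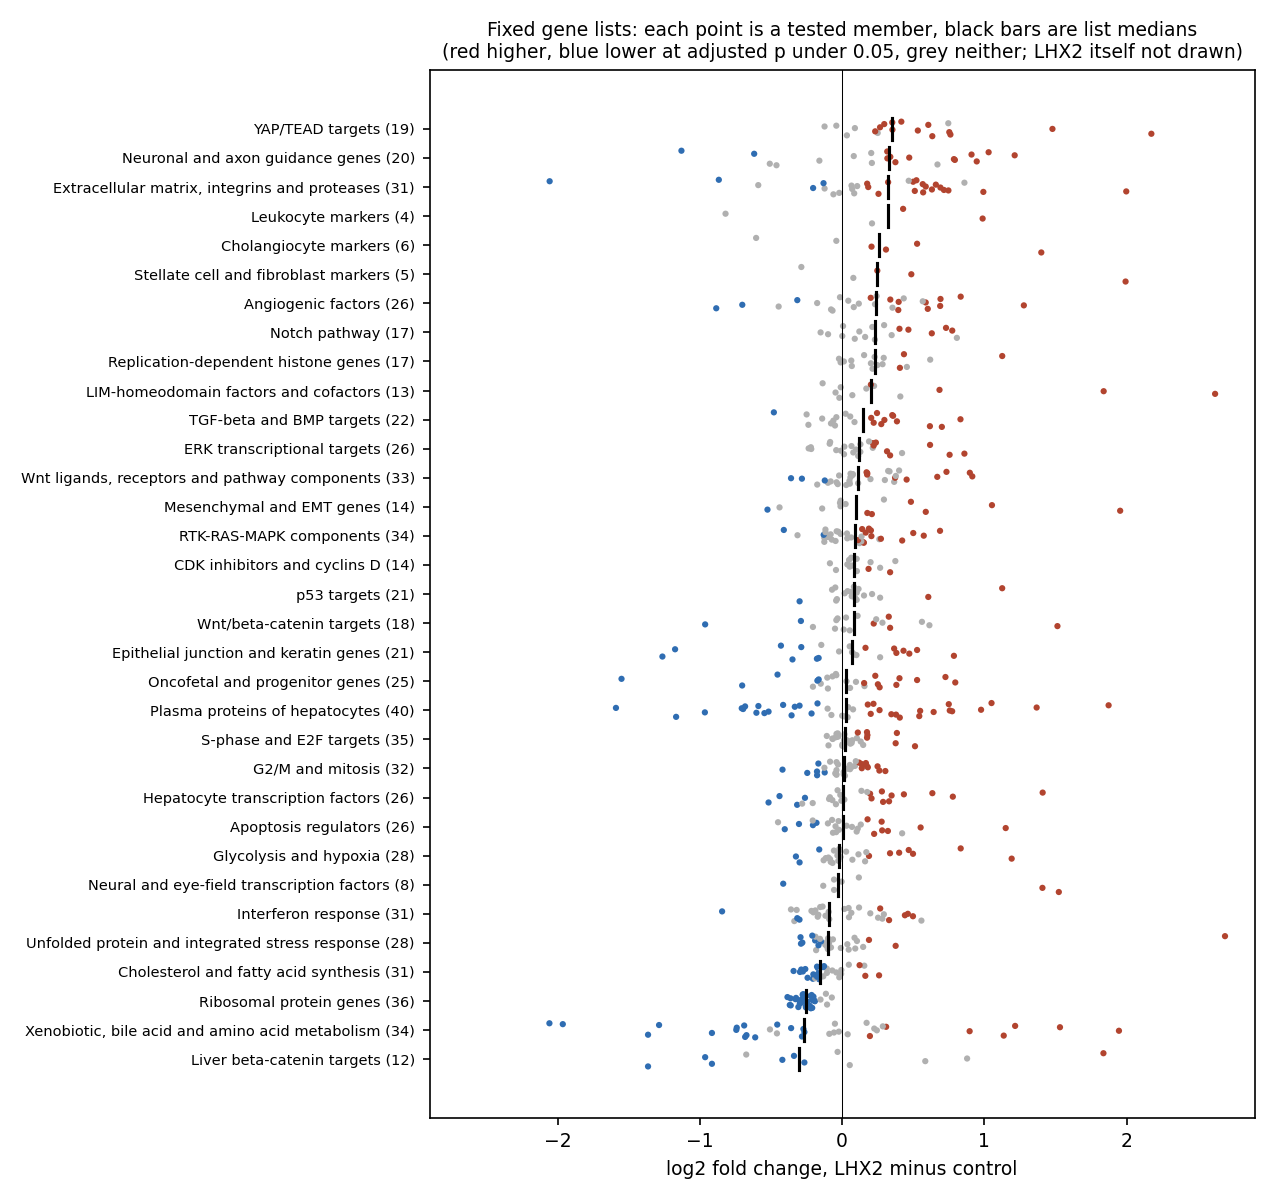
Log2 fold change, LHX2 minus control, of each tested member of the 33 gene lists (points; red higher, blue lower, grey neither in the edgeR test), ordered by list median (black bars), with the number of tested members in parentheses and LHX2 left out. YAP/TEAD targets (median 0.35) lie at the top, and ribosomal protein genes (median -0.25) form the tightest group below 0.

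Of the 33 lists tested 7 passed camera at an adjusted p under 0.05 with the preset correlation, and 0 did with an estimated correlation, where 3 lists had an unadjusted p under 0.05. fry, which asks whether a list's own genes move on balance one way without comparing them with other genes, called 25 lists. The count by camera was 11 without control replicate 1 and 12 without LHX2 replicate 2.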

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

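Of the tests in this part, the removal of the length and GC trend was chosen after the results were seen, as were the leave-one-out runs for genes outside the naming rule and for the counts within lists. No named gene or list test past the threshold changed direction under any alternative. List tests that did not pass could change direction, as those of the plasma protein, interferon and epithelial lists did after the centred trend removal, and the plasma protein and interferon lists also by fry. Among named genes 2349 values kept their side of the threshold, 54 lost the threshold and 2 gained it. Among list tests 526 kept it, 53 gained it and 15 lost it. The count of changed genes lay between 3549 (without control replicate 2) and 5179 (length and GC trend removed, not centred), with 4112 in DESeq2, 4058 of them shared, and 4715 in limma-voom. The count of genes changed at least 2-fold, LHX2 vs control, was 366 to 396 with 1 library left out and 122 in glmTreat, which tests against 2-fold. Against 7 lists past the threshold there were 11 without a filter on low counts, 12 with a replicate block, 25 by fry, and 6 to 12 in leave-one-out runs, including 11 without control replicate 1 and 12 without LHX2 replicate 2. camera with an estimated correlation passed 0 lists (3 at an unadjusted p under 0.05). The adjusted p of the ERK target list was 0.049 with the 1 CPM filter, 4.8e-03 by fry, and 0.027 (without LHX2 replicate 2) to 0.18 (without LHX2 replicate 1) in leave-one-out runs, passing also without control replicate 1 (0.042). That of the Wnt target list was 0.013 by fry, which tests the list's own movement, and 0.22 to 0.62 in leave-one-out runs. For the filters, the block, the estimated correlation and the left-out libraries the cause was not tested. The neuronal and LIM-homeodomain lists had estimated correlations of -0.041 and -0.040, below the preset 0.01. Their unadjusted camera p nevertheless rose from 9.7e-04 to 0.023 and from 1.2e-03 to 0.027. A higher correlation between members thus does not account for their loss. The other lists that had passed had estimated correlations of 0.045 to 0.37. The replicate block lowered the count of changed genes to 3768, 3761 of them shared. Libraries with the same number did not deviate together (correlations of -0.06, -0.07 and -0.19, against -0.07 to 0.13 for other pairs). This cannot exclude that the numbers pair libraries, since deviations from the mean of 3 libraries constrain each other. Depth and 3 libraries per group limit the detection of small changes. In the simulation 23 of 50 1.2-fold changes were recovered, but it held far fewer changed genes than were called here. Its adjusted threshold was therefore stricter, and that share does not give the sensitivity in these data.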

Other observations

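The gene families, the single genes named next and the tests on scaling, pseudogenes, other cell types, feedback inhibitors and splits of the genes changed were chosen after the results were seen. Many genes of translation and mitochondrial import were lower (Fisher's exact tests in 14 families and both directions, Benjamini-Hochberg adjusted, against 15.8% of all tested genes lower). These p-values are descriptive, since the families were picked on the same data and the test treats genes that move together as independent. Lower were 43 of 77 mitochondrial ribosomal protein genes (adjusted p = 2.3e-14), 15 of 17 cytosolic tRNA synthetase genes (8.7e-10), 27 of 50 translation initiation factor genes (3.8e-09), 17 of 24 TIMM and TOMM genes of mitochondrial protein import (1.5e-08) and 14 of 23 SNHG genes, which host small nucleolar RNAs (5.5e-06). The metal-binding metallothioneins were lower in 7 of 8 cases (5.3e-05), with log2 fold changes of -1.13 for MT1G, -0.70 for MT1X and -0.67 for MT1E, as were 7 of 8 genes of the CCT chaperonin (5.3e-05). Collagen genes were higher in 10 of 20 cases (1.3e-03) and clustered protocadherin beta genes in 8 of 14 (1.4e-03). These directions held under all 5 scalings of the libraries. Close copies within the metallothionein and protocadherin beta families may share reads, which leaves values of their single genes uncertain. Of the other families, 15 of 37 proteasome genes (6.9e-04), 14 of 38 complex I genes (2.7e-03) and 6 of 10 aldo-keto reductase genes (3.2e-03) were lower, and solute carriers did not pass in either direction. Zinc finger genes were called less often than other genes, with 45 higher and 27 lower of 469, or 66 and 14 with library totals alone. Genes with more counts pass more easily, and the families were not matched for expression. More or fewer calls in a family therefore need not mean more or fewer changes.

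Some regulators outside the fixed lists also rose. How many regulators rose or fell in all was not counted, so a joint rise of pathway inhibitors was not tested. CTNNBIP1, which binds beta-catenin and blocks its contact with TCF factors, rose 3.22-fold from 24.2 ± 0.828 CPM (SD, n = 3) in the control libraries (edgeR adjusted p = 3.7e-11). TLE4, a corepressor of TCF factors, had a log2 fold change of 1.21, DACT2, a Dishevelled-binding protein gene, 1.01, and ERRFI1, an inhibitor of EGF receptor signalling, 0.86. A2M, the plasma protease inhibitor alpha-2-macroglobulin, rose from 1334 to 3057 CPM. The transcription factor genes CASZ1 (2.13), TBX2 (1.78) and RARB (1.11) rose too.

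The fall of the ribosomal protein genes (median log2 fold change -0.25) was weighed against technical explanations. It was not removed with the length and GC trend (median -0.20, with 32 of 36 still lower). That test was set before its first form was run and altered by centring afterwards. Lengths were those of the longest annotated transcripts (median 1846 bases for this list), which may differ from the transcripts expressed, so a length trend stays possible. The 5 scalings moved the median only between -0.26 and -0.22, so scalings this alike could not remove the fall. Ribosomal pseudogenes gained 0.0785% of what the genes lost, so reads moving to them account for little, although the size asked of that gain was chosen after the ratio was seen. A candidate explanation is a lower output of MYC factors, since MYCN fell. A list of MYC-activated nucleolar and growth genes was drawn up after both falls were seen and before its values were. In it 41 of 50 were lower, with a median of -0.29 (camera adjusted p = 3.0e-14, but adjusted p = 0.30 with an estimated correlation). Nucleolar and growth genes may fall together with ribosomal protein genes whatever the cause, so this list cannot tell MYC factors from other causes. A lower output of MYC factors is a hypothesis: MYCN went from 96.0 to 32.8 CPM, and MYC moved the other way by less, from 19.8 to 23.1 CPM (log2 fold change 0.22, edgeR adjusted p = 0.034), a call that did not pass without control replicate 1 (0.25), control replicate 3 (0.15) or LHX2 replicate 1 (0.18).

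Markers of fibroblasts and leukocytes rose in part, which contaminating cells could bring. The summed counts of COL1A1, COL3A1, DCN, POSTN and PDGFRB had an LHX2 to control ratio of 0.648 (exact binomial 95% interval 0.427 to 0.971, 40 against 68 counts), while the ratio of COL1A2 was 4.06 (3.78 to 4.37). Within that sum COL1A1 had a ratio of 1.47 (0.804 to 2.72) and COL3A1 of 0.367 (0.143 to 0.845). Those of PTPRC, CD74, HLA-DRA, LAPTM5 and CSF1R had a ratio of 0.612 (0.378 to 0.973, 30 against 54 counts), against 2.03 (lower bound 1.86) for CD68, although PTPRC alone, with 3 against 2 counts, decides nothing (1.65, 0.189 to 19.8). Both sums were chosen after the values were seen and leave out LUM, PDGFRA and LYZ, which rose, so they cannot exclude such cells. They show only that COL1A2 and CD68 rose without a matching rise of the summed genes, at the low counts given. A change of COL1A2 and CD68 within the Huh7 cells stays open and was not tested.

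The rise of ERK targets was weighed against a length and GC trend and against a rise of feedback inhibitors alone. After the trend was removed 8 of the 8 members that had risen still passed, 1 other member was called lower, and the list as a whole again did not pass camera (adjusted p = 0.058). This argues against a trend with the lengths used, those of the longest annotated transcripts, as the whole account of those 8 genes. Outside the DUSP, SPRY and SPRED genes 4 of 18 members rose (22.2%, against 16.6% of all other genes; one-sided Fisher's exact p = 0.35), and of those 8 inhibitors 4 rose, so a rise carried by the inhibitors alone stays open. These RNA counts hold no measure of ERK phosphorylation, so from them whether the pathway's activity changed stays open too.

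The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split, the 1 with the largest result for each of these, gave 4716 genes changed, 2415 higher, 2301 lower and 373 at least 2-fold, and the highest of the other splits gave 0 for each (edgeR; 115 to 803 genes at an unadjusted p under 0.05, against 6164). Each other split puts LHX2 and control libraries in both arms. The difference between the vectors then becomes spread within the arms, which by itself removes calls. The 0 calls therefore say nothing about chance or false calls in the real split. For the lists past the threshold the real split gave 7 and the highest other 6.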
